A study of Drosophila melanogaster with 3 samples.

How the data were processed

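Chromatin immunoprecipitation with sequencing was done on whole white prepupae of a fly line that carries pdm3 with a C-terminal GFP, in 3 biological replicates that form 1 group. Per the labels, the chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP. The control library that the authors name was not analysed here, and neither were reads or signal tracks. The aligner, the peak caller and the threshold on reproducibility are not given in the sources used here.

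The deposited lists are in narrowPeak format on dm6 and dm3. Per the labels' readme, each replicate's candidate list derives from that library's alignments and 1 control file, the pooled candidate list from all 3 replicates, and the optimal list from candidate lists by an analysis of the irreproducible discovery rate. Each candidate list holds 30000 rows. The signal value of each peak is the authors' own, its normalization is not stated, and it was used only to rank peaks within a list. The deposited −log10 of the q-value ran from 2.49 to 4.08 in the optimal list on dm6 and was not used to select peaks. No depth per library is given in these lists, so no limit from depth could be computed, and intervals on shares cover counting error over peaks or genes only. No rows were identical between replicate lists.

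All coordinates are on dm6 and counted from 1. Arm names and peak ends were compared with the RefSeq sequence of the same assembly, and no peak ran past the end of its arm. Genes came from Ensembl release 115, with 13945 protein-coding genes and 19607 start sites on the 6 arms X, 2L, 2R, 3L, 3R and 4. Replicates were compared by coverage of at least 50% of a peak. Sharing was set against 100 random placements within arms, and signal values between replicates were taken from the highest overlapping peak. Summits were put in the first class that applied of within 500 bp of a start site, 5' UTR, coding exon, 3' UTR, intron and intergenic, and were tested against 100000 random positions outside assembly gaps. Genes counted as bound with a summit within 1 kb of a start site. Motifs were sought on both strands in windows of 101 bp around summits and around a point 500 bp to a randomly chosen side. Two-sided exact binomial, Fisher's exact and exact McNemar tests were used, each family adjusted by Benjamini and Hochberg, with 0.05 as the threshold. Tests over peaks and genes of pooled lists measure the spread over the genome, not between animals, so shares from each replicate's own list stand beside some of the main ones.

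The tests, the 21 gene lists, the 17 motifs, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 25 genes with the highest summit within 1 kb of the nearest start site that is covered in all 3 replicate lists, pdm3, up to 4 bound and 2 unbound members per list, and the 10 highest peaks. Of 503 list symbols 23 were not symbols of the annotation and were dropped, as the rule set in advance says. The first runs departed from that rule and matched older symbols by synonym, and 5 more were matched by hand after list results had been seen. The rule set in advance was then restored for the main results, also after list results had been seen, and because the choice changes which lists pass, the other counts are given separately. Alternatives covered the overlap, list depth, sets without 1 replicate, stricter peak sets, distances, backgrounds and matched random lists (10000 per list). For arms, classes, lists, motifs and the pdm3 locus, peaks were not called again from fewer libraries. Without replicate 1, for example, means the optimal peaks covered by the equally long top of both other replicates' lists. Such a set is a stricter selection from the pooled list, so a shift there is not an effect of the named replicate alone.

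The tests were run on simulated data first. With 3 lists per run raised to 60% bound genes, 86.0% of them were called in 100 runs, and 0.722% of the other lists. An octamer planted in 2.96% of random windows gave a difference of 3.06 percentage points. Besides the octamer and its half-site, which were not counted, 0 motifs were called, and 0 classes were called among random positions. Random positions lack the GC difference between real summits and flanks, and all genes outside the raised lists had the same chance of being bound. These rates of false calls therefore do not carry over to the real summits and lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.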

Results

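Binding of pdm3, a POU-homeodomain transcription factor known for its part in the specification of olfactory neurons, was mapped in whole white prepupae of Drosophila melanogaster, the stage at which the larva becomes immobile at the start of metamorphosis. The flies carried pdm3 with a C-terminal GFP, and chromatin sheared to 200 to 800 bp was precipitated with an antibody against GFP and sequenced. The series holds 3 biological replicates of mixed sex in 1 group, and no other group to set against them. For each replicate the authors deposited a list of 30000 candidate peaks, and for the replicates pooled a list of the same length together with a shorter list of reproducible peaks, called optimal here. The lists give no read counts, so the depth of each library is unknown. Signal values below are the authors' own per-peak values, used only to rank peaks within a list.

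The optimal list on dm6 held 8164 peaks with a median width of 420 bp and widths up to 1099 bp. Their signal value ran from 89.8 to 4114, with a median of 173. These peaks were the 8164 highest of the pooled candidates by signal value. The authors' optimal list on dm3, which was not converted, held 7777 peaks.

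The strongest peaks lay at genes of varied function. The highest optimal peak, 3L 19590403 to 19590846, had its summit 99 bp from the start site of CG14100 and a signal value of 4114. The peak at 2L 480827 to 481347, with a signal value of 4027, lay in an intron of ush, which encodes a zinc-finger cofactor of GATA factors, and 1376 bp from the nearest start site, that of cbt. Next came peaks 40 bp from the start site of Ugalt (X 2703678 to 2704114, signal value 3655), in an intron of CG11050 (2L 6612464 to 6612926, 3405) and 79 bp from the start site of PNPase (3R 31404446 to 31404888, 3389). The sixth, 2R 13035099 to 13035578, was intergenic, 11918 bp from the start site of CG13323. The last 4 of the 10 highest peaks were assigned to Lk6, Chro, larp and CG8320, with signal values from 2913 to 2970. Chro encodes a chromodomain protein found between the bands of polytene chromosomes.

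Among the 25 protein-coding genes with the highest summit within 1 kb of a start site, 21 had that summit within 500 bp of a start site and 4 in an intron. All 25 ranked within the first 70 peaks of each replicate. They included ph-p, a Polycomb group gene (X 2136948 to 2137609, signal value 2408), with a mean rank in the top 0.0611% ± 0.0164 of the replicate lists (SD, n = 3). Hsp27, a small heat shock gene (3L 9383693 to 9384121, 1966), lay in the top 0.144% ± 0.0771 (SD, n = 3). HmgZ, which encodes a high mobility group protein, had a summit 528 bp from a start site with a signal value of 2324, and mRpL41, for a mitochondrial ribosomal protein, one at 143 bp with 2573. The other genes named by this rule were Tcs5, CenG1A, CG18549, CG4496, CG1888, Art3, GstE13, CG9663, CG9147, CG31145, gish, Fkbp14, Pdrg1 and CG8360. For 11 of the 25 genes the summit also lay within 1 kb of a start site of another gene, so the gene it belongs to is uncertain.

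How far the replicates shared these peaks was asked by overlap. Replicate 3 covered 98.4% of the optimal peaks over at least 50% of their length, replicate 1 covered 97.7% and replicate 2 covered 94.6%, a mean of 96.9% ± 2.01 (SD, n = 3). All 3 covered 91.2% (95% Wilson interval 90.6 to 91.8%), against a mean of 3.06% and a highest value of 3.49% for 100 random placements of the peaks within their arms. The optimal peaks come from an analysis of reproducibility of these same libraries, so coverage above random follows in part from how they were selected. With each replicate list cut to its 8164 highest peaks, the share covered by all 3 was 62.3% (61.3 to 63.4%). With whole lists and an overlap of at least 80% it was 61.3%. Of the 8164 highest peaks of replicate 1, 5269 (64.5%, 63.5 to 65.6%) were covered by the equally long top of both other lists, a comparison without that selection, against a mean of 1.31% for random placements. Across optimal peaks, which are not independent replicates, Spearman's rho of the signal values was 0.87 between replicates 1 and 3, 0.80 between 1 and 2, and 0.80 between 2 and 3.

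**Figure D1:**
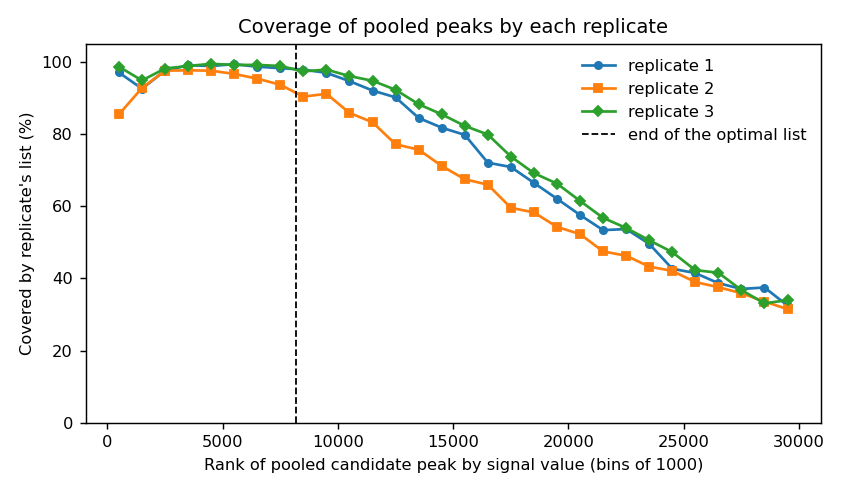
Share of pooled candidate peaks covered over at least 50% of their length by each replicate's list (y axis, percent), in bins of 1000 ranks by signal value (x axis), 1 line per replicate, with the end of the optimal list dashed. In the first bin the shares were 97.1%, 85.5% and 98.7% for replicates 1, 2 and 3, and in the last bin 32.5%, 31.5% and 34.0%. Replicate 2 covered 97.6% at ranks 2001 to 3000, so its coverage was lower among the strongest peaks.

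Peaks were spread over all chromosome arms, but not in proportion to length. The X chromosome carried 1679 peaks, 20.6% of the list (95% Wilson interval 19.7 to 21.5%) for 17.6% of the length, 1.17-fold more than its share (two-sided exact binomial test, Benjamini-Hochberg adjusted p = 2.38e-11). Arm 2R carried 1331 peaks, 0.863-fold its share (exact test, adjusted p = 2.59e-09). The small chromosome 4 carried 31 peaks, 0.377-fold its share (exact test, adjusted p = 4.08e-10), and 0.195-fold in the higher-signal 50% of peaks, in peaks in the top of all 3 lists and without replicate 1 or 3. Here and below, a set without a replicate holds the optimal peaks covered by the top of both other replicates' lists. Those peaks were still called from all 3 libraries. Arm 3R, with 1854 peaks, was at 0.948-fold (exact test, adjusted p = 0.0118), a call that ended in the higher-signal 50% of the peaks (0.960-fold, adjusted p = 0.229), with peaks in the top of all 3 lists and without replicate 2. Arms 2L and 3L, each 1.04-fold, did not pass the threshold. The 3 replicates' candidate lists placed 17.9%, 16.5% and 20.2% of their peaks on X, for replicates 1, 2 and 3. On chromosome 4, with 1.01% of the length, they placed 0.85%, 0.313% and 1.0%. Of the sets at 0.195-fold there, all but the higher-signal 50% required coverage by replicate 2, the lowest of these.

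Most pdm3-GFP summits lay within 500 bp of a start site or in introns, and few lay in coding exons farther from one. Of the optimal summits 28.0% (95% Wilson interval 27.1 to 29.0%) were within 500 bp of a start site of a protein-coding gene, 2.45-fold the share of random positions in the same arms, 11.5%. Introns held 47.2% of summits against 39.2% of random positions, and intergenic sequence 23.2% against 30.1%. Coding exons beyond 500 bp of a start site held 16 summits, 0.196% (0.121 to 0.318%), where random positions gave 13.8%. Summits in coding sequence nearer to a start site were counted as near start sites and were not told apart. The 3' UTRs held 0.784% against 4.57%, and 5' UTRs 0.563% against 0.802%. All 6 classes passed the two-sided exact binomial test, with adjusted p = 0.0153 for 5' UTRs, 4.0e-89 for 3' UTRs and 2.21e-48 for introns; for start sites and coding exons p lay below the smallest number the software holds. The equally long top of the replicates' own lists gave 30.8% ± 1.20 near start sites and 0.167% ± 0.0495 in coding exons (SD, n = 3). Set against the lower pooled candidates instead of random positions, the intron share was 0.961-fold rather than 1.20-fold, a change of direction. In that comparison coding exons were at 0.180-fold rather than 0.0142-fold and 3' UTRs at 0.486-fold rather than 0.172-fold, because the lower candidates too held few summits there, 1.09% in coding exons. Introns held 49.1% of the lower candidates, and 39.7% of the 1000 highest optimal summits, near the share of random positions. Because the 6 class shares sum to the whole, the shortfall in exons raises the intron share. The 1.20-fold over random positions therefore does not by itself show a preference for introns.

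**Figure D2:**
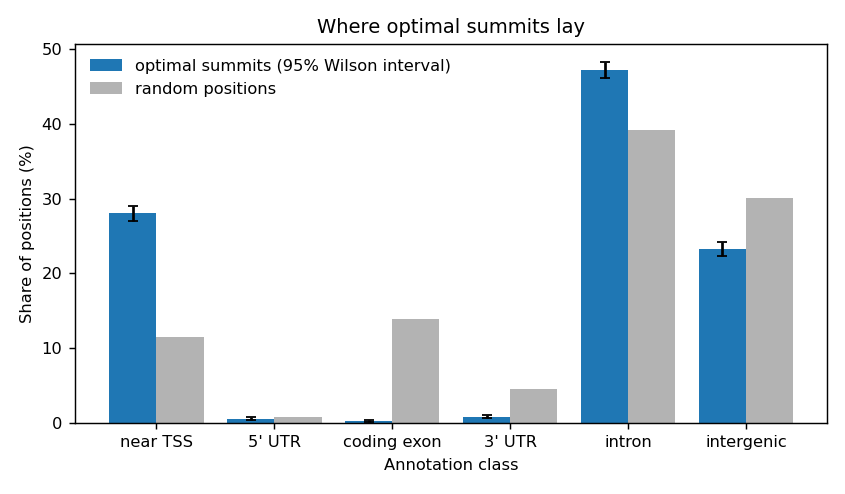
Share of optimal summits in 6 annotation classes (blue bars, percent, with 95% Wilson intervals) beside the share of random positions (grey bars). Summits near start sites made up 28.0% against 11.5%, and those in coding exons farther from a start site 0.196% against 13.8%.

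Which genes carried a summit within 1 kb of a start site was asked for 21 gene lists fixed in advance. Of 13945 protein-coding genes 2965 had one, 21.3%. Of the summits within 1 kb of a start site, 28.6% lay that near to start sites of more than 1 gene. By two-sided Fisher's exact tests 4 lists were bound more often than the other genes, 3 less often, and 14 did not pass.

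Genes for cytosolic ribosomal proteins stood highest. A summit lay at 30 of 43 (69.8%, 95% Wilson interval 54.9 to 81.4%), against 21.1% of other genes, an odds ratio of 8.62 (Fisher's exact test, adjusted p = 2.38e-10). The strongest were at RpS27 (3R 25247371 to 25247766, signal value 675), RpL32 (3R 30046106 to 30046516, 635), RpL7 (588) and RpS20 (555), while RpL6 and RpL9 had none. Each of these 4 summits also lay within 1 kb of a start site of another gene, and the one at RpS20 had no rank in replicate 2. The top of the replicates' own lists gave 71.3% ± 7.48 (SD, n = 3). Against random lists matched on gene length and number of start sites, which averaged 21.0%, the list still passed (permutation by random draws of genes, adjusted p = 0.0042).

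Regulators of the response to ecdysone, the steroid hormone whose pulses drive metamorphosis, were bound at 14 of 22 genes (63.6%, 43.0 to 80.3%), an odds ratio of 6.51 (Fisher's exact test, adjusted p = 0.000219). The strongest were at Eip75B, a nuclear receptor gene (3L 17999620 to 17999972, signal value 724), usp, the partner of the ecdysone receptor (X 2041398 to 2041528, 304), Eip63E (289) and Eip74EF, an ETS factor gene (286). The summit at usp lay within 1 kb of start sites of 3 genes, so the gene it belongs to is uncertain. Eip78C and Hr4 had no summit within 1 kb of a start site, though 5 and 13 lay inside these genes. These genes tend to be long with several start sites: matched random lists averaged 47.2%, and against them the list no longer passed (permutation, adjusted p = 0.329). In the higher-signal 50% of peaks the call ended, at 36.4% against 14.2% of other genes (exact test, adjusted p = 0.0564).

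Axon guidance and adhesion genes were bound at 14 of 34 (41.2%, Fisher's exact test, adjusted p = 0.0459), though at 14.7% against 14.2% of other genes in the higher-signal 50% of peaks, the strongest being unc-5, a netrin receptor gene (2R 15349876 to 15350156, signal value 563), dlp (316), PlexA (272) and Toll-7 (201), with robo1 and robo3 without one. Heat shock and stress genes were bound at 8 of 17 (47.1%, exact test, adjusted p = 0.0473, a call that also ended within 5 kb and with gene bodies), among them Hsp27, Hsp26 (762), stv (577) and Hsc70-5 (533), while Hsp70Aa and Hsp70Ab had none. Cuticle protein genes had 0 of 27 (upper Wilson bound 12.5%, exact test, adjusted p = 0.0229), though 9 within 5 kb and 3.70% ± 3.70 in the top of the replicates' lists (SD, n = 3), with Lcp1 and Lcp2 among those without. Salivary glue and prepupal gland genes had 0 of 20 (upper bound 16.1%, exact test, adjusted p = 0.0459), Sgs1 and Sgs3 among them. Chemoreceptor genes had 1 of 31 (3.23%, exact test, adjusted p = 0.0459), Or88a (3R 14108493 to 14108912, 170), and not Orco or Or22a. The summits at Or88a, dlp and Hsc70-5 also lay within 1 kb of a start site of another gene. None of these 5 lists passed against matched random lists (permutation, adjusted p between 0.0748 for chemoreceptors and 0.488 for axon guidance), though the difference shrank little for heat shock genes (24.5 percentage points after matching, 25.8 before) and chemoreceptors (-15.7, -18.1), and more for axon guidance (to 7.36), cuticle (-12.8, -21.3) and glue genes (-9.53, -21.3). None passed with peaks required in the top of all 3 replicate lists, nor in any set without 1 replicate. Cuticle and glue genes, though, had 0 in each of those sets, and heat shock genes had 7 of 17 without replicate 3. The exact tests, Wilson bounds and matched lists take genes as independent. Members of a list can be neighbours, such as Lcp1 (2R 8430115 to 8431243) and Lcp2 (2R 8433797 to 8434785). For such lists the bounds may be too narrow and the p-values too small.

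Among lists that did not pass, the nearest to the threshold were the Notch pathway with the E(spl) genes, glia and the circadian clock (each exact test, adjusted p = 0.0544). In the first, 9 of 20 genes had a summit, with fng (signal value 882), E(spl)m3-HLH (626), E(spl)m7-HLH (473) and numb (468) highest. It passed against matched random lists, which averaged 19.3% (permutation, adjusted p = 0.0483), but its excess of 23.8 percentage points came to 9.19 without replicate 3 and 13.9 without replicate 1. Glial genes had 7 of 15, with moody (812) and Gli (386) highest and repo and gcm without one. Clock genes had 6 of 12, with sgg (1043), cry (404) and vri (340), and without tim and Clk. Fat body genes had 8 of 18 (exact test, adjusted p = 0.0700), led by Lpin, for a phosphatidate phosphatase (1555), and bmm, for a triglyceride lipase (458). Fat body genes passed within 500 bp and 5 kb of a start site, and the Notch list within 5 kb (exact tests, adjusted p = 0.0265, 0.0441 and 0.0212). The clock list came to 3 of 12 in each set without 1 replicate. With older gene symbols matched by synonym, as in the first runs, all 4 passed as higher, and with 5 more symbols matched by hand, after the results had been seen, Notch and glia did not.

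The regulators of olfactory neuron specification had 4 of 21 genes with a summit, Xbp1 (signal value 372), pdm3 itself (253), dac (178) and dan (92.5), and acj6 and vvl had none. Chromatin came from whole animals. Binding confined to a small part of the cells, here or at chemoreceptor genes, might not reach the optimal list, which was not tested. Neuronal excitability and synapse genes had 6 of 30, among them dnc (1170) and elav (1136). Within 1 kb of a start site para and Shal had none, though each held 1 inside the gene. Muscle genes had 4 of 25, with sls (496) and Zasp52 (326), and not Mhc or Act57B. These 3 did not pass (exact tests, adjusted p between 0.751 and 1). Against matched random lists, which averaged 45.7% and 40.5%, the excitability and muscle lists were bound less often (permutation, adjusted p = 0.0315 and 0.0483). Selector and patterning regulators had 10 of 33 in the optimal list, but 9.09%, 39.4% and 12.1% in the top of replicates 1, 2 and 3. Counting summits anywhere in the gene or within 1 kb of it, they had 20 of 33 and passed (exact test, adjusted p = 0.00064). Neural fate regulators had 7 of 28, led by elav and grh (413). Ecdysteroid synthesis had 1 of 12 (mld), hemocytes 2 of 16 (PPO3 and ush), midgut 2 of 19 (Pdp1 and cad), germline and testis 3 of 24 (bgcn, bcd and can) and pigmentation 2 of 13 (speck and bi). The summits at mld and PPO3 also lay within 1 kb of a start site of another gene.

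**Figure D3:**
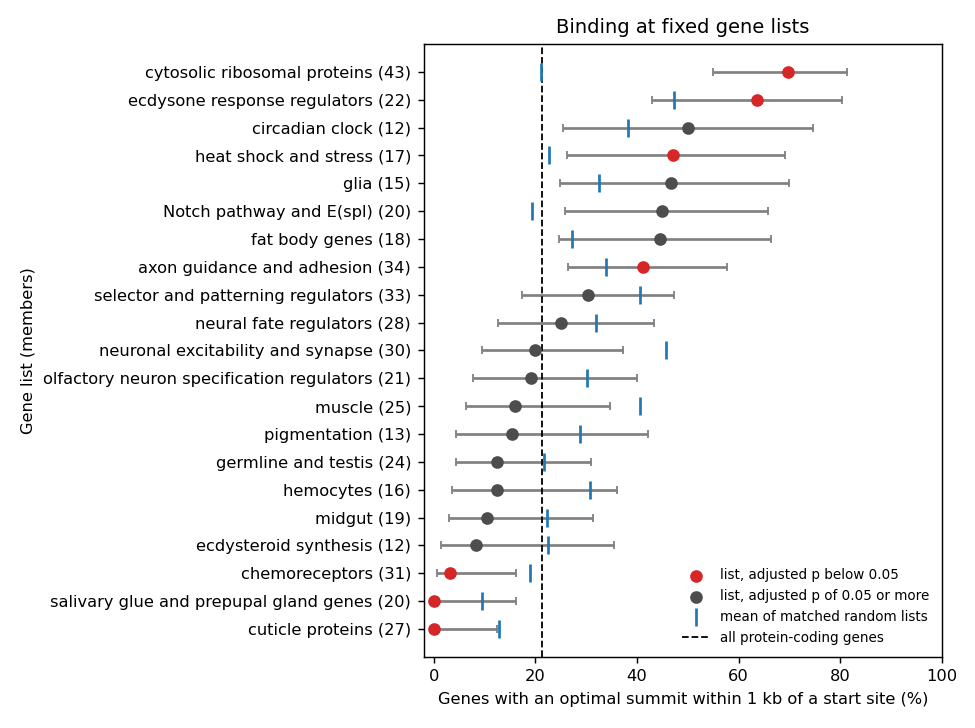
Percent of genes with an optimal summit within 1 kb of a start site (x axis) for each gene list (members in brackets), with 95% Wilson intervals as bars. Red points passed Fisher's exact test, blue ticks mark the mean of matched random lists, and the dashed line marks all protein-coding genes at 21.3%.

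Whether summits carry the octamer bound by POU factors, or other known motifs, was asked for 17 fixed sequences. The octamer ATGCAAAT occurred within 50 bp of 1.59% of summits and in 1.92% of flanks 500 bp away (exact McNemar test, adjusted p = 0.191). In windows of 100 bp to either side it was less frequent at summits, 2.93% against 4.02% (exact test, adjusted p = 0.00053). The half-site ATGCAA occurred at 819 summits and in 833 flanks (exact test, adjusted p = 0.782). The promoter element TATCGATA, bound by the factor DREF, was 4.00-fold more frequent at summits, 0.784% against 0.196% (exact test, adjusted p = 2.0e-07). It passed under every alternative run, at 1.95-fold against lower candidates to 8.25-fold in the higher-signal 50% of peaks. There the summit share hardly moved, to 0.808%, and the fold rose because fewer flanks held the word, 0.098%. None of the backgrounds was matched for distance to start sites. Of the optimal summits 28.0% lay within 500 bp of one, and of the lower candidates 14.1%. Frequency of TATCGATA at summits was therefore not separated from its frequency at promoters. Another core promoter motif, GTCACACT, did not pass at 1.89-fold (exact test, adjusted p = 0.0510; 3.10-fold without replicate 2 and 4.14-fold without replicate 3), but passed in the higher-signal 50% of peaks, in the top of all 3 lists, without replicate 2 or 3, with 100 bp windows and against shuffled windows, and not without replicate 1, with flanks 1 kb away or against lower candidates. The homeodomain core TAATTA was at 10.1% of summits against 6.12% of flanks (exact test, adjusted p = 2.36e-19), and TAATGAG was at 1.73% against 1.15% (exact test, adjusted p = 0.00636). The call for TAATGAG ended in the higher-signal 50% of peaks with the fold unchanged (1.51), in the top of all 3 lists, without replicate 3, with 100 bp windows and against lower candidates, and that for TAATTA ended against lower candidates (1.08-fold). The control sequence AAGCTAAT, which itself ends in the core TAAT, also passed, 1.97-fold more frequent (exact test, adjusted p = 0.00713) and 3.07-fold without replicate 1. The sequences CACACACA (0.247-fold), CACCTG (1.83% against 4.05%), CAGCTG (0.535-fold) and GAGAGA (0.749-fold) were less frequent at summits (exact tests, adjusted p from 2.86e-35 to 0.000112). The call for GAGAGA ended in the top of all 3 lists, with 100 bp windows, with flanks 1 kb away and against lower candidates, and replicate 2's own top gave 1.12-fold.

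Base composition differed between summits and flanks, with 33.0% GC at summits, 43.5% in flanks and 42.2% at random positions; the top of the replicates' own lists had 33.7% ± 1.46 (SD, n = 3). Against dinucleotide-shuffled copies of the summit windows, a background chosen after the data were seen, TATCGATA was 4.00-fold more frequent (exact test, adjusted p = 3.33e-07). TAATTA turned to 0.880-fold, and the control AAGCTAAT to 1.00-fold. GAGAGA, CACACACA and CAGCTG turned to 1.80-fold, 2.72-fold and 1.94-fold more frequent. The other control, ATGACAAT, was then 0.525-fold (exact test, adjusted p = 0.0101), so on each of these backgrounds, flanks and shuffled windows, a control sequence passed. Against lower candidates neither control passed (exact tests, adjusted p = 0.591 and 0.541).

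**Figure D4:**
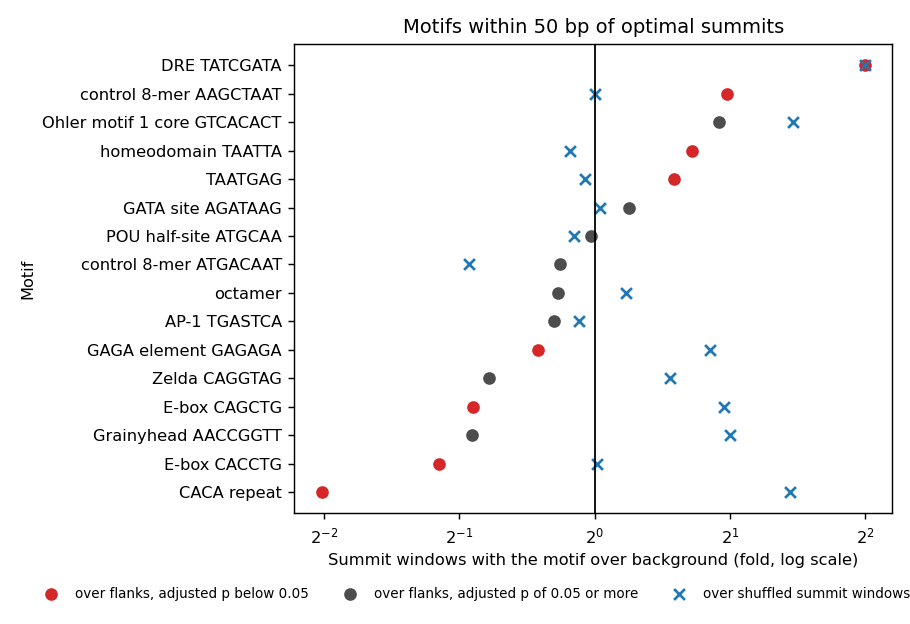
Fold of optimal summit windows with each motif over flanks (points, red where the exact McNemar test passed) and over dinucleotide-shuffled summit windows (blue crosses), on a log axis. TATCGATA was at 4.00-fold over both backgrounds, while TAATTA lay at 1.65-fold over flanks and 0.880-fold over shuffled windows.

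At pdm3 itself (2R 8327490 to 8396280, plus strand), 6 optimal summits lay inside the gene and 11 inside it or within 10 kb. The peak at 8327185 to 8327604 had its summit 95 bp from the upstream start site of pdm3, with a signal value of 253 and a mean rank in the top 11.6% ± 6.90 of the replicate lists (SD, n = 3). The highest, 8357985 to 8358220 (429, top 4.17% ± 0.319), was in the gene but 433 bp from the start site of CG11635. Upstream of pdm3, the intergenic peak at 8321940 to 8322294 had a signal value of 361 (top 5.28% ± 0.589). Of 1505 genomic windows of the same size, 84.7% held fewer optimal summits than this one, and 96.6%, 94.8% and 98.1% held fewer candidates of replicates 1, 2 and 3. The flies carry a tagged copy of the gene, and the lists do not tell its peaks from those of the endogenous locus. Where that copy is extra to the endogenous one, the added DNA alone could raise the counts, which was not tested. The counts are therefore not read as binding of pdm3 at its own gene.

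**Figure D5:**
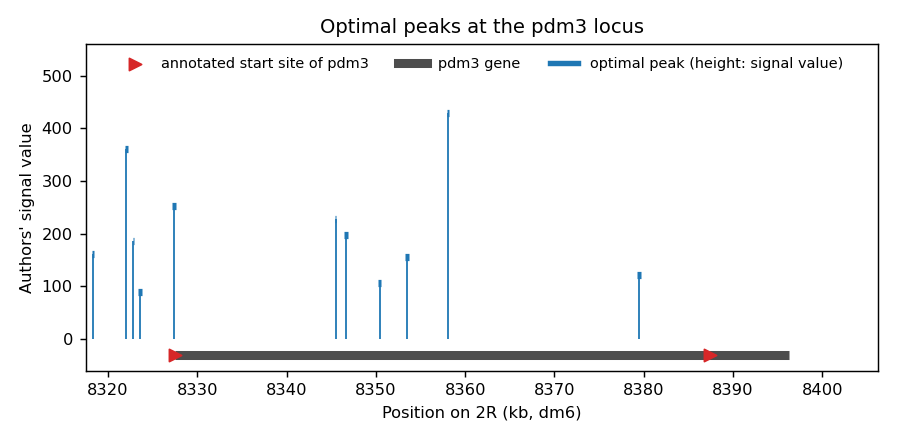
Optimal peaks from 10 kb upstream to 10 kb downstream of pdm3 on 2R (x axis, kb, dm6), drawn at the height of the authors' signal value (y axis). The gene is the grey bar and its start sites are red arrowheads. The highest of the 11 peaks, at 429, lies inside the gene.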

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

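Both counts below were chosen for attention after the results were seen. On dm3, 4 peaks of the optimal list lay outside the 6 arms, on XHet, 3LHet and Uextra, sequences the comparisons did not use; they are named because there were more than 3, and since no number was predicted, nothing was tested. The highest, on XHet at 49992 to 50411, had a signal value of 197 and rank 3439. Outside the optimal list on dm6, 142 of 21836 pooled candidates were covered by the 8164 highest peaks of all 3 replicates, named for the same reason. Their median pooled rank was 13786, and 26.1% of them lay within 500 bp of a start site.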

How the results depend on the processing

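The hand matching of 5 gene symbols and the shuffled summit windows were chosen after results were seen; synonym matching was unplanned and used in the first runs, before list results were seen, and all other alternatives were planned. The share of optimal peaks covered by all 3 replicates was 97.4% with an overlap of 1 bp, 61.3% with 80%, 62.3% in the top of each list, 88.6% in the higher-signal 50% of peaks, and 92.5 to 96.3% without 1 replicate. The replicates' own set went from 64.5% to 70.8% and 47.6% with overlaps of 1 bp and 80%, and to 68.9 to 79.3% without 1 replicate; rho lay between 0.80 and 0.87. Without replicate 2 agreement was highest in each of these; the cause was not tested. Arm 3R lost its call in the higher-signal 50% (0.960-fold) and with peaks in the top of all 3 lists (0.949-fold), and without replicate 2 (0.959-fold, adjusted p = 0.111, exact test), and was at 0.946 without replicate 1, where it held; arm 2L ranged from 1.02 to 1.07 and passed without replicate 3. The intron fold turned to 0.961 against lower candidates, of which 49.1% lay in introns against 39.2% of random positions. Coding exons came to 0.180-fold and 3' UTRs to 0.486-fold against lower candidates, and chromosome 4 to 0.195-fold in the higher-signal 50%, in the top of all 3 lists and without replicate 1 or 3. The pdm3 locus kept 6 of 11 summits in the higher-signal 50%. The dm3 arm shares were not tested because dm3 arm lengths were not used here.

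Against 7 lists past the threshold in the main analysis, 1 passed in the higher-signal 50% of peaks (1 higher, 0 lower), and 2 in the peaks in the top of all 3 lists and without any replicate (2 higher, 0 lower), in part because those sets hold fewer peaks (4082 to 6190). With older symbols matched 11 passed (8 higher), with 5 more matched by hand 9, and against matched random lists 4 (2 higher, of which Notch had not passed before, and 2 lower, excitability and muscle, which had not either). Within 500 bp, within 5 kb and with gene bodies 7 lists passed each, but not the same ones: glue genes ended at 500 bp (still 0 of 20), cuticle genes at 5 kb, heat shock genes at 5 kb and with gene bodies, while fat body genes passed at 500 bp and 5 kb, Notch at 5 kb and selectors with gene bodies (32.4 points). The Notch list, 23.8 points, came to 9.19 without replicate 3, 13.9 without replicate 1 and 5 of 20 genes in the top of all 3 lists, and axon guidance to 10.7 without replicate 3 and 0.458 in the higher-signal 50%. The clock list, 28.8 points, came to 6.94 to 9.19 without 1 replicate and 1.67 in the top of all 3 lists. Ribosomal protein genes passed under every alternative run. In percentage points over other genes, lists that had not passed changed direction as follows, the cause not tested. In the higher-signal 50% of peaks, olfactory specification came to 0.0369, neural fate to -3.54 and selectors to -14.3. With peaks in the top of all 3 lists, excitability came to 1.68, neural fate to -4.29, muscle to 1.01 and selectors to -12.0. Without 1 replicate, excitability ranged from -1.40 to 4.19, neural fate from -7.36 to 1.78, muscle from -2.07 to 0.181 and selectors from -12.8 to -8.99. Within 5 kb, neural fate came to -2.89 and muscle to 1.83. With gene bodies, olfactory specification came to 9.81, excitability to 15.1, muscle to 7.72 and pigmentation to 2.47. Against matched lists, neural fate came to -6.86 and selectors to -10.4.

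Against 8 motifs past the threshold in the main analysis, 4 passed against lower candidates (1 higher, TATCGATA). Against shuffled windows, which keep the composition of the summit, the fold turned to 1.17 for the octamer, 0.880 for TAATTA, 0.953 for TAATGAG, 1.80 for GAGAGA, 2.72 for CACACACA, 1.47 for CAGGTAG, 1.94 for CAGCTG, 1.01 for CACCTG and 2.0 for AACCGGTT. On that background 8 motifs passed, 5 higher, among them GTCACACT (2.77-fold), and 3 lower, among them ATGCAA (0.899-fold). The octamer passed as less frequent with 100 bp windows (0.729-fold), and so did AACCGGTT (0.395-fold). Without replicate 1, CAGGTAG passed as less frequent (0.488-fold) and AGATAAG as more frequent (1.49-fold). TGASTCA passed as less frequent without replicate 2 and in the top of all 3 lists (0.554-fold in each). TATCGATA passed throughout, at 2.50-fold without replicate 1, 1.95-fold against lower candidates and 8.25-fold in the higher-signal 50%, where only 0.098% of flanks held it. No alternative was matched for distance to start sites, so a preference for promoters was not separated. TAATGAG lost its call in the higher-signal 50% (1.51-fold, unchanged), in the top of all 3 lists (1.26-fold), without replicate 3 (1.35-fold), with 100 bp windows (1.14-fold) and against lower candidates (1.05-fold). The control AAGCTAAT came to 3.07-fold without replicate 1 and 3.14-fold in the top of all 3 lists, and GTCACACT to 3.10-fold and 4.14-fold without replicates 2 and 3. GAGAGA came to 1.05 with 100 bp windows, and lost its call in the top of all 3 lists, with flanks 1 kb away (0.911-fold) and against lower candidates (0.866-fold). ATGCAA came to 1.03 with flanks 1 kb away and ranged from 0.965 to 1.03 without 1 replicate. The control ATGACAAT came to 1.095 in the top of all 3 lists, 1.04 with 100 bp windows and 1.0 to 1.26 without 1 replicate. No depth is known, so what depth limits could not be computed.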

Other observations

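The gene families here were chosen by symbol after the list results were seen, and so were the tests of the exon pattern, the word CACTG itself and its comparison with shuffled windows; the other tests for CACTG and those for ribosomal protein genes were set down before they were run. Of 14 families, mitochondrial ribosomal protein genes were bound more often, 25 of 73 (34.2%, Fisher's exact test, adjusted p = 0.0147), and against matched random lists, which averaged 11.2% (adjusted p = 0.00093). Proteasome subunits, by contrast, had 3 of 48 (6.25%, exact test, adjusted p = 0.0135). Against matched lists, which averaged 16.4%, that call ended (permutation, adjusted p = 0.131). Translation initiation factors with 9 of 44, complex I subunits with 8 of 40 and vacuolar ATPase subunits with 6 of 33 did not pass. Chemosensory receptor families were low: 2 of 59 odorant receptors, 0 of 60 gustatory receptors (upper Wilson bound 6.02%) and 1 of 60 ionotropic receptors, each also below matched lists (permutation, adjusted p = 0.0224, 0.00093 and 0.00093). With chromatin from whole animals, binding at these genes in a small part of the cells might be missed. Odorant-binding proteins had 3 of 51 (exact test, adjusted p = 0.0123) but did not pass against matched lists (permutation, adjusted p = 0.325). The Cpr cuticle proteins, some of which are in the cuticle list, had 6 of 70 (8.57%, exact test, adjusted p = 0.0135). Against matched lists, which averaged 14.2%, they did not pass either (permutation, adjusted p = 0.352). In all 9 families were bound less often than other genes, and 3 of them also against matched lists.

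Some long genes held many optimal summits. The most were in kirre (39 in 394 kb), CG43658 (29), sbb (29 in 79.1 kb), CG1677 (23), Tet, which encodes a DNA hydroxylase (22), shn (22 in 58.3 kb) and Ptp61F (21). Per length, shn with 3.77 and sbb with 3.67 summits per 10 kb exceeded kirre with 0.989. Replicate 2 stood apart in the lists: it had 676 coding-exon summits among its candidates, against 307 and 346 in replicates 1 and 3, and 35.3% GC in the top of its list against 32.7% and 33.0%.

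Few summits lay in the coding-exon and 3' UTR classes, which leave out positions within 500 bp of a start site. Base composition was tested by comparing positions of equal GC share: coding positions lay within 100 bp of a summit 0.0391 times as often as intron positions (95% interval 0.0228 to 0.0669), and 3' UTR positions 0.0852 times as often, which argues against composition as the whole cause. Coding sequence was not wholly left out of the authors' lists: the replicate with the fewest such candidates had 307, 1.02% of its list. The optimal list already held 16 such summits, so this outcome was settled beforehand. Whether coding sequence was left out in part was not tested. Open chromatin outside exons, as any precipitation might show it, stays open, since no control precipitation was analysed here. No biological explanation was tested, because the design has 1 group.

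The word CACTG, on either strand, was noticed in a scan of words in summit windows against shuffled copies, and then beside summits. It occurred in 31.9% of windows centred 100 bp to either side, in 19.5% at the summit and in 16.7% at 500 bp, a ratio of 1.91 (95% bootstrap interval 1.83 to 1.99) that was 1.89, 1.75 and 1.81 in the top of replicates 1, 2 and 3. Beside summits the share was 2.15 times that in shuffled windows, which is no independent test of base composition, since a comparison with shuffled windows had found the word. Annotated transposable elements lay near only 98 optimal summits, 1.20% of them, too few to account for much of the pattern. Leaving out so few peaks could hardly move the ratio, which stayed at 1.91, so the outcome of that test was settled beforehand. The remaining test argues against a property of AT-rich islands whether bound or not, since unbound islands showed 9.21% of the excess. Those islands were narrower in their GC dip than summits, with 43.2% GC against 39.9% at 100 bp to the right. A candidate explanation is a sequence bias at fragment ends, which lists without reads cannot test, or paired sites around the bound position; both stay open, and the pattern is a hypothesis found and tested on the same data.

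Binding at ribosomal protein genes was not matched by gene length and number of start sites, since 0% of 10000 matched random lists were bound as often, with a highest value of 46.5%. The same held for promoter base composition, where 0% of lists matched on GC share reached it and the highest was 48.8%. The comparison on gene length and start sites repeats, with new draws, the one given in the Results, and is no separate test. Promoter GC was 40.1% in these genes and 41.8% in all genes. Activity of the promoters, and precipitation of open chromatin by the antibody without pdm3, might each account for it and were not tested. No biological explanation was tested.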
